A study of Mus musculus with 2 samples.

How the data were processed

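DNase-seq maps the stretches of chromatin that the enzyme DNase I cuts readily, which include active promoters and regulatory regions. The 2 libraries were made from kidney tissue of female mice 10 days old, F1 hybrids of the B6 and CAST strains, and the sample notes name 3 females for each library. Per the labels, both belong to 1 group, are biological replicates with separate biosample entries, and carry 1 donor entry, so whether the animals were littermates is not known. There is no second group, so no comparison of conditions was possible, and values describe these libraries with n = 2 at most.

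Per the notes the authors deposited with each sample, the files are peak lists in narrowPeak form, footprints and a list of the false discovery rate of DNase cutting, all on the assembly mm10, derived library by library from filtered alignments. Nuclei were isolated from tissue, per the labels' protocols. The aligner, the peak caller, the footprint caller, their versions and the thresholds are not given in the sources used here. The deposited peak signal is a peak height on a scale that the files do not name. The weaker signal values were tested for equal steps, 130866 of 162711 peaks in replicate 1 and 114653 of 137084 in replicate 2, and the strongest were not. All tested values were whole multiples, within a tolerance of 0.05 of a step, of 1 step per library, 0.00535 in replicate 1 and 0.00323 in replicate 2. Equal steps are what counts scaled to a fixed total would give, and if that total were 1 M the steps would stand for 187 M counts in replicate 1 and 310 M in replicate 2. However, the scale and the read totals are not stated and the depth is unknown. The deposited q-value (false discovery rate) file lists bases below 0.05. Each library has 2 peak lists. In the longer list every peak held a base with a rate under 0.05, and in the shorter list under 0.001, tested on the files. The longer lists were used. The score column of the footprint lists is 1 constant, so only footprint positions were used. The peak signal is the authors' own value per peak, and because the libraries were called and scaled separately, folds between them are on the deposited scale only.

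Chromosome lengths of the reference sequence GRCm38 were checked against the file coordinates, and genes were taken from GENCODE release M21 (basic set), using 21 chromosomes. All 41354 transcription start site (TSS) positions of 21800 protein-coding genes were used, after 27 symbols shared by several genes were left out. A promoter peak is a peak within 1 kb of any TSS of the gene, and the promoter signal is that of the strongest such peak. Before taking log2 values 0.1 was added, so a gene with no peak has a log2 value of -3.32. Promoter CpG content is the ratio of observed to expected CpG within 500 bp of a TSS. Overlapping peaks of the libraries were merged into regions, called shared when both libraries had a peak in them and distal when they lay over 1 kb from every TSS. Peaks were called overlapping at 1 bp or more, and 100 random placements of the peaks within their chromosomes gave the chance overlap. Peak locations were assigned in the order promoter, exon, intron, between genes.

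The gene lists (23 lists with 315 genes, all found in the annotation), the 33 consensus sequences, and the main tests and alternatives were fixed before the data were examined. Tests and alternatives that were added later are named as such below. The lists hold markers of proximal tubule, loop of Henle, distal convoluted and connecting tubule, collecting duct principal cell, intercalated cell, podocyte, nephron progenitor and early nephron, ureteric epithelium, endothelium, and stroma and mural cells. Cell types of other tissues make up a further set: immune cell, erythroid cell, hepatocyte, neuron, striated muscle, germ cell, lung, gut and pancreas epithelium, adrenal gland and adipocyte. Nuclear receptors, cell cycle, housekeeping and Y-linked genes complete them. The rule for named genes took, from each list of kidney cells or functions, the 3 members with the highest mean log2 promoter signal among those open in both libraries. It also took up to 2 members, in alphabetical order, with no promoter peak in either. From each list of another tissue it took the 2 highest, and it added the 10 strongest shared distal regions and the 3 listed genes with the largest promoter ratio between the libraries in each direction. Not every gene and region that the rules selected is reported, and the figure of named promoters shows the strongest of each list that the text names.

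Promoter peaks of a list were set against all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 23 lists, at 0.05. As an alternative, a two-sided resampling test set the list's open share against 10000 random lists, adjusted in the same way. These lists were drawn with replacement from other genes of the same deciles of promoter CpG content. Promoter signal, distal regions within 50 kb of a TSS, and the log2 ratio between libraries were each given as the percentile of the list's median or mean among 10000 random lists of the same size. The random lists were matched by decile on promoter CpG content, on gene density and on mean signal respectively. A list was called when its percentile lay in the outermost 2.5% at either end, with no correction over lists. Genes and regions are not replicates, so these p-values and percentiles describe the libraries and carry no error between animals. Consensus matches per base were counted on both strands, in shared distal regions against flanks of the same length 1 kb away on each side, which were not cleared of other peaks. They were also counted in bases that both libraries marked as footprint against bases that neither marked. This count covered all shared regions with bases marked by both, promoter regions included, and not distal regions alone. A match overlapping bases marked by both by 1 bp counted as inside. One clear of the footprints of both libraries counted as outside, and all other matches counted in neither. The 1 bp rule favours the inside count for any word, so each ratio was set beside those of up to 20 shuffled consensus sequences. Intervals on the ratios are exact 95% (Clopper-Pearson) intervals and cover counting error only.

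On simulated data, 6.6% of unchanged lists of 14 genes passed either percentile limit, 80.4% of lists raised by 1.5 on the log2 scale did, and CpG-rich unchanged lists passed in 5.6% with matching and 67.6% without. The Fisher test called 2.7% of unchanged lists at an unadjusted 0.05 and 100% of lists with all members open, and all 300 planted consensus sites were found. A difference between promoter and distal ratios made by GC content alone, 0.48 on the log2 scale, fell to 0.02 after matching on GC content, and a true difference of 0.5 was returned as 0.52. With 1 common factor between the libraries, a noisier replicate 2 and weak regions lost, the log2 ratio differed by 0.03 between the sixth and the ninth decile of signal, and with a factor that grew with signal by -0.45.

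Alternatives covered the overlap rule, the stronger 50% of peaks, the same number of peaks per library, promoter distances of 500 bp and 2000 bp, and distances of 20 kb and 100 kb for distal regions. They also covered matching or not matching, the scaling between libraries, flanks 5 kb away, a consensus wholly inside the footprint, and leaving out each library. The shorter peak lists, a single TSS per gene, and library ratios only where the strongest promoter peaks overlap were added after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1, with the random seed 1. The maternal and paternal alleles were not separated, and reads were not analysed here.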

Results

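Open chromatin was mapped by DNase-seq in the kidney of female B6CASTF1/J mice aged 10 days, in 2 biological replicates. Replicate 1 had 162711 peaks covering 30.2 Mb and replicate 2 had 137084 peaks covering 25.2 Mb, with a median width of 180 bp in each. The median deposited peak signal was 0.631 in replicate 1 and 0.504 in replicate 2, and 9.49% and 3.25% of the peaks lay above a signal of 5. Footprints, the short stretches inside open regions where a bound protein shields the DNA, numbered 401604 in replicate 1 and 356680 in replicate 2. The series holds 1 group, so the questions that could be addressed were how far the replicates overlapped, which genes and regions were open in both, and where the libraries differed.

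The strongest open regions were nearly all found in both libraries, while weak ones were mostly seen once. Of the replicate 1 peaks 58.7% overlapped a replicate 2 peak, and of the replicate 2 peaks 69.7% overlapped a replicate 1 peak, a mean of 64.2%, against 2.01% and 2.45% for randomly placed peaks. In the strongest decile of peaks 98.9% of replicate 1 and 99.0% of replicate 2 were shared, and in the weakest decile 18.8% and 2.32%. Merging gave 200966 regions, of which 93546 were open in both libraries, 66575 in replicate 1 only, with a median signal of 0.374, and 40845 in replicate 2 only, with a median signal of 0.229. Across shared promoter regions the log2 signals had a Pearson r of 0.92, and across shared distal regions 0.71, with Spearman rho of 0.92 and 0.69. Over all 200966 regions, including those open once, r was 0.56 and rho 0.53. These correlations are across regions, which are not independent replicates.

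**Figure D1:**
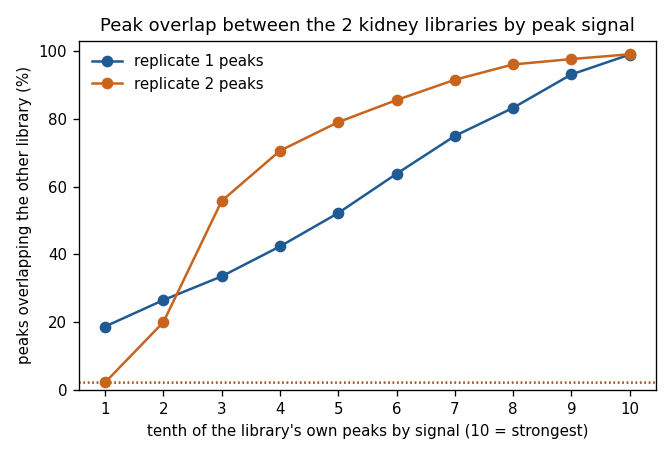
Share of each library's peaks (y axis, %) that overlapped a peak of the other library, by decile of the library's own peak signal (x axis, 10 = strongest), with dotted lines at the mean for randomly placed peaks. Sharing rose from 18.8% to 98.9% in replicate 1 and from 2.32% to 99.0% in replicate 2.

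Promoters were the most over-represented part of the genome. Regions within 1 kb of an annotated TSS held 23.8% ± 0.862 of the peaks (SD, n = 2) and 4.38% of the sequence, a ratio of 5.44. Exons held 5.36% ± 0.116 of the peaks, 1.84 times their share of the sequence, introns 38.4% ± 1.89 (ratio 0.955) and the space between genes 32.5% ± 1.14 (ratio 0.618). Of the 21800 protein-coding genes, 14547 (66.7%) had a promoter peak in both libraries, and 27.3% had none in either. Openness followed promoter CpG content, from 4.27% of genes in the lowest decile to 97.9% in the highest.

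Markers of the filtering unit and of the developing nephron were open in nearly every case. Of the podocyte markers, 14 of 15 had a promoter peak in both libraries. Among them were Podxl, the podocyte sialoprotein podocalyxin (7.79 in replicate 1 and 2.99 in replicate 2), and Synpo, the actin-associated protein synaptopodin (6.14 and 2.60). Col4a3 and Col4a4 in that list had identical values (3.24 and 0.985), so the podocyte results count what appears to be 1 shared peak as 2 genes. Counting it once was not tested. Nephron progenitor and early nephron genes were also open in 14 of 15 cases. Jag1, a Notch ligand, stood at 11.9 and 3.20, Pax8, a transcription factor of kidney formation, at 5.61 and 1.88, and Sall1, a zinc-finger factor of the progenitors, at 6.04 and 1.54. The adjusted p was 0.0495 for each list (Fisher's exact test against 66.7% of other genes), and it became 0.0740 without replicate 1, 0.0743 with promoters of 2000 bp and 0.160 with promoters of 500 bp. The nephron progenitor list also missed the threshold with the stronger 50% of peaks (0.0868) and the shorter peak lists (0.0823). Ureteric epithelium markers were open in 10 of 11 cases, led by Etv5 (20.03 and 13.0) and Etv4 (6.30 and 3.74), transcription factors downstream of the Ret receptor, and Spry1, an inhibitor of that pathway (15.5 and 3.65). The list did not pass the test (Fisher's exact test, adjusted p = 0.154). In a permutation against random lists of like CpG content, podocyte and nephron progenitor genes did not stand apart (adjusted p = 0.376 and 0.971), since CpG-matched lists were 80.5% and 87.8% open.

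Lists of mature tubule segments ran from 58.3% to 91.7% open, and none passed the test against all genes in both libraries together. In the proximal tubule list 19 of 28 promoters were open (Fisher's exact test, adjusted p = 1). The water channel gene Aqp1 had 3.26 in replicate 1 and 2.42 in replicate 2, in a peak on chromosome 6 from 55336021 to 55336460 in replicate 1, over the TSS at 55336432. The endocytic receptor megalin, Lrp2, had 4.20 and 1.65 and the gluconeogenic enzyme Pck1 2.76 and 1.67, whereas Acsm2 and Kap had no promoter peak in either library. The loop of Henle list had 11 of 13 open. Egf, the epidermal growth factor gene, stood at 9.98 and 4.03, the transcription factor Irx2 at 4.30 and 2.38, and the tight junction protein Cldn19 at 1.80 and 1.46, while Cldn14 was closed. This list did not pass against all genes (Fisher's exact test, adjusted p = 0.293), but in a permutation it was more often open than lists of like CpG content, 84.6% against 50.7% (adjusted p = 0.0151). The other tubule lists did not pass that permutation (adjusted p = 0.0593 for proximal tubule, 0.0754 for principal cell, 0.896 for distal convoluted and 0.971 for intercalated cell genes). Distal convoluted and connecting tubule genes were open in 8 of 11 cases. The kinase gene Wnk1 stood at 19.3 and 5.85, Emx1 at 4.47 and 1.12, and the calcium-binding protein Calb1 at 3.10 and 0.762, and the sodium-calcium exchanger gene Slc8a1 had no promoter peak. Principal cell genes of the collecting duct were open in 11 of 12 cases. Tfcp2l1 stood at 9.06 and 1.56, the sodium channel subunit gene Scnn1g at 7.02 and 1.08, and the water channel gene Aqp3 at 2.76 and 0.768. That list did not pass in both libraries together (Fisher's exact test, adjusted p = 0.105) and passed without replicate 2 (adjusted p = 0.0402). Intercalated cell genes were open in 7 of 12 cases, led by Insrr (2.27 and 1.03), the ammonia transporter gene Rhbg (2.75 and 0.823) and Dmrt2 (2.21 and 0.959), with Aqp6 and the proton pump subunit gene Atp6v1g3 closed. Neither intercalated nor distal convoluted genes passed (Fisher's exact test, adjusted p = 0.631 and 1). With the stronger 50% of peaks the distal convoluted list was open less often than other genes (27.3%; Fisher's exact test, adjusted p = 0.0470), and with the shorter peak lists the intercalated list was (25%, adjusted p = 0.0250).

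Every endothelial and stromal marker was open in both libraries. All 16 endothelial promoters had a peak in both libraries (Fisher's exact test, adjusted p = 0.00592). Ehd3, a membrane-trafficking gene of glomerular endothelium, stood at 10.2 and 4.53, the TGF-beta co-receptor endoglin, Eng, at 5.31 and 3.09, and the VEGF receptor Kdr at 4.56 and 1.89. All 15 stroma and mural cell promoters were open as well (Fisher's exact test, adjusted p = 0.00853). They were led by the collagen gene Col1a1 (9.601 and 2.96), the homeobox gene Meis1 (5.92 and 4.59) and the growth factor receptor gene Pdgfra (8.73 and 2.46). At Col1a1 and Pdgfra the strongest peaks of the libraries did not overlap, so each pair of values describes different elements. CpG-matched random lists were open in 66.6% and 60.1% of cases, and both lists stood above them by permutation (adjusted p = 0.00368 and 0.00115, the latter from the smallest p that 10000 random lists can give). With a single TSS per gene the endothelial list did not pass (adjusted p = 0.103, Fisher's exact test), nor did the stromal list with the stronger 50% of peaks (adjusted p = 0.0868).

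Markers of other tissues were mostly closed. No promoter of the 14 immune cell genes was open in both libraries, although Spi1, the myeloid factor PU.1, had a peak of 0.491 and the chemokine receptor Cx3cr1 one of 0.323 in replicate 2 alone. Likewise, none of the 14 lung, gut and pancreas genes was open in both, with Cdx2 at 0.497 and Pdx1 at 0.374 in replicate 1 alone. The adjusted p was 2.32e-06 for each of these lists (Fisher's exact test). Without replicate 2, 35.7% of the lung, gut and pancreas genes were open, and without replicate 1, 21.4% of the immune and 20% of the germ cell genes, shares that were still lower than in other genes (Fisher's exact test, adjusted p = 0.0149, 0.00359 and 0.00213). Germ cell genes were open in 1 of 15 cases (adjusted p = 1.6e-05, Fisher's exact test), the exception being the RNA-binding protein gene Dazl (10.7 and 3.60), while the meiotic gene Sycp3 had only a replicate 2 peak of 0.368. Adrenal genes were open in 2 of 13 cases, chromogranin A, Chga (8.62 and 1.26), and the cholesterol transporter Star (1.49 and 0.665), with an adjusted p of 0.00119 by Fisher's exact test, and 30.8% were open without replicate 2. The hepatocyte and striated muscle lists each had 4 of 15 open (Fisher's exact test, adjusted p = 0.00509). The apolipoprotein gene Apob stood at 3.54 and 0.488, Itih1 at 3.60 and 0.426, the myosin light chain gene Mylpf at 16.0 and 7.02, and the calcium channel gene Ryr1 at 1.82 and 0.817, where the Mylpf values come from peaks that did not overlap. Erythroid genes were open in 3 of 12 cases (adjusted p = 0.00853, Fisher's exact test), including the erythropoietin receptor gene Epor (3.87 and 2.22) and Tal1 (1.54 and 0.978). The Apob, Itih1, Star, Epor and Chga peaks lay within 1 kb of a TSS but not over it. The same was true of the Spi1 peak in replicate 2, the Cdx2 peak in replicate 1 and the Mylpf peak in replicate 1. With promoters of 500 bp, 20% of the hepatocyte and 7.69% of the adrenal genes were open (Fisher's exact test, adjusted p = 0.00205 and 0.000158). Neuronal genes were not depleted, with 10 of 15 open, among them the synaptic genes Snap25 (8.55 and 1.28) and Syn1 (3.58 and 2.10). Adipocyte genes had 5 of 11 open, led by the lipase gene Lipe (14.7 and 6.59) and Cidea (1.93 and 0.688). Neither list passed Fisher's exact test (adjusted p = 1 and 0.251). The Snap25 and Cidea peaks also lay within 1 kb of a TSS but not over it. The adipocyte list was open less often than other genes with the stronger 50% of peaks (18.2%; exact test, adjusted p = 0.0119) and with the shorter peak lists (27.3%, adjusted p = 0.0389). Against lists of like CpG content the immune, germ cell and lung, gut and pancreas lists remained less often open (permutation, adjusted p = 0.0151, 0.00115 and 0.00115). The adrenal, hepatocyte, muscle and erythroid lists did not (permutation, adjusted p = 0.0593, 0.946, 0.50 and 0.971).

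Broadly used genes had strong promoters in both libraries. All 17 housekeeping promoters were open (Fisher's exact test, adjusted p = 0.00509), led by the elongation factor gene Eef2 (32.5 and 9.40), the actin gene Actb (29.4 and 7.71) and Vcp (18.99 and 9.68). All 10 nuclear receptor and all 10 cell cycle promoters were open too, with an adjusted p of 0.0566 each (Fisher's exact test). Both lists passed the exact test with promoters of 500 bp (adjusted p = 0.0328) and with a single TSS per gene (0.0344), and cell cycle genes also with the stronger 50% of peaks (0.0181) and the shorter peak lists (0.0280). Esrra, the oestrogen-related receptor, had the highest value of the named promoters, 36.9 in replicate 1 and 18.2 in replicate 2 (chromosome 19, 6921801 to 6922020 in replicate 1). The mineralocorticoid receptor gene Nr3c2 (14.8 and 8.96) and Ppara (18.8 and 5.07) followed among the receptors. Cyclin A2, Ccna2, had 24.02 and 9.17, Mcm5 19.2 and 8.31, and Pcna 17.2 and 9.06. The housekeeping list was not more often open than lists of like CpG content (permutation, adjusted p = 0.899).

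**Figure D2:**
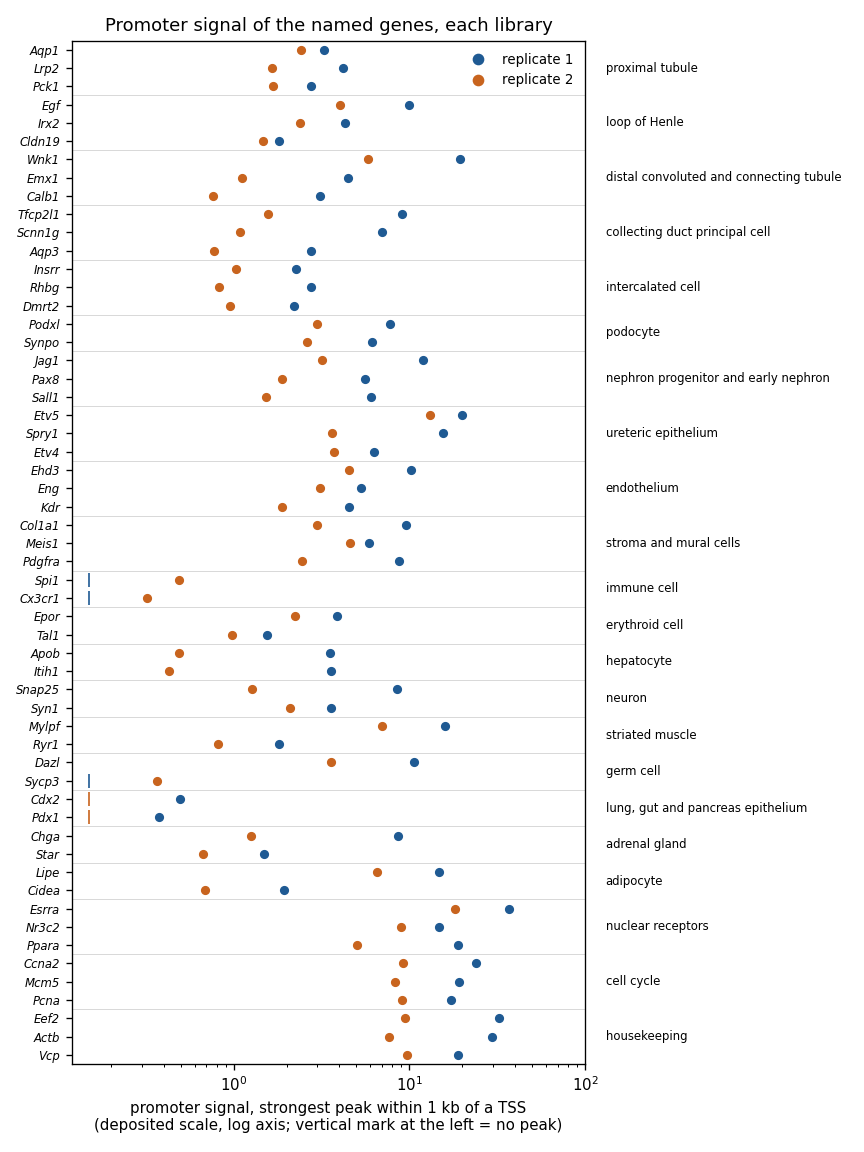
Promoter signal of the strongest named genes of each list (x axis, deposited scale, log axis) in replicate 1 (blue) and replicate 2 (orange), grouped by list, with a vertical mark at the left edge where a library had no peak. Values run from 0.323 for Cx3cr1 in replicate 2 to 36.9 for Esrra in replicate 1.

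Measured by signal, housekeeping promoters stood highest and nephron progenitor promoters stood low for their CpG content. The housekeeping list had a median log2 promoter signal of 3.49 against 2.64 in CpG-matched random lists, at percentile 99.9. Nephron progenitor and early nephron genes had 0.54 against 2.34 (percentile 0.33, and 1.875 without replicate 1) and neuronal genes -0.40 against 1.79 (percentile 0.3). Neither was called without matching on CpG content (percentiles 33.3 and 15.8). The germ cell list, at percentile 1.57, had a median at the value for no peak, -3.32, and was not called without replicate 1 (percentile 5.57), with the shorter peak lists (4.53), with promoters of 500 bp (2.585) or with a single TSS per gene (2.66). Y-linked genes, at percentile 0, also had no peaks. The remaining lists were not called: proximal tubule lay at percentile 96.0, stroma and mural cells at 93.5, cell cycle at 88.4, loop of Henle at 85.8, and endothelium at 81.2. Lower lay adipocyte genes at percentile 62.0, intercalated cell at 53.7, nuclear receptors at 36.1, principal cell at 25.4, distal convoluted tubule at 17.0, podocyte at 12.5 and ureteric epithelium at 10.5. Immune, erythroid, hepatocyte, muscle, adrenal and lung, gut and pancreas genes had medians at the value for no peak, where most percentiles are ties and carry no information. Proximal tubule genes passed with a single TSS per gene (percentile 97.9), and ureteric epithelium fell to 2.39 with promoters of 500 bp and to 1.12 with a single TSS per gene.

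Shared distal regions were more numerous near genes of several kidney lists, and of the nuclear receptor list, than near genes of random lists. Ureteric epithelium genes had a mean of 10.2 shared distal regions within 50 kb, against 3.64 in random lists of like gene density (percentile 99.98), and endothelial genes 8.75 against 4 (percentile 99.99). The loop of Henle list had 7.38 (percentile 99.1), podocyte 6.67 (98.6), stroma and mural cells 6.67 (99.0), nephron progenitor 6.27 (99.2) and proximal tubule 5.82 (99.0), where all protein-coding genes had a mean of 4.07 and a median of 3. Single genes with many such regions included the gluconeogenic gene Pck1, with 23, Synpo with 21, Eng with 15 and Cldn14, whose own promoter was closed, with 14. Nuclear receptor genes had 7.1 (98.7), with 13 regions near Ppara. Distal convoluted tubule (3.73), principal cell (4.42) and intercalated cell genes (5.17) lay within the range of random lists, at percentiles 41.2, 66.2 and 86.9. So did the lists of other tissues, from hepatocyte genes at 2.6 (percentile 8.19) through germ cell (3.2), erythroid (3.33), neuron (3.33), lung, gut and pancreas (3.86), adrenal (4.08), immune (4.29) and muscle (5.13) to adipocyte genes at 5.73 (percentile 85.5). Cell cycle (5.8) and housekeeping genes (6.29; percentile 96.3) were within that range too. Cell cycle genes were called within 100 kb (percentile 99.2), housekeeping genes without matching (97.6) and with a single TSS per gene (97.6), and hepatocyte genes within 20 kb, below the random lists (0.38). Y-linked genes had 0. Without replicate 1 the nuclear receptor, stroma and nephron progenitor lists were not called (percentiles 96.1, 91.7 and 97.4). Within 100 kb the podocyte and nephron progenitor lists were not called either (96.9 and 95.1). The same held for nuclear receptors (96.7) and nephron progenitor genes (96.8) within 20 kb, loop of Henle (96.7) and nuclear receptor genes (97.3) with a single TSS per gene, and nephron progenitor genes without matching (96.5).

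**Figure D3:**
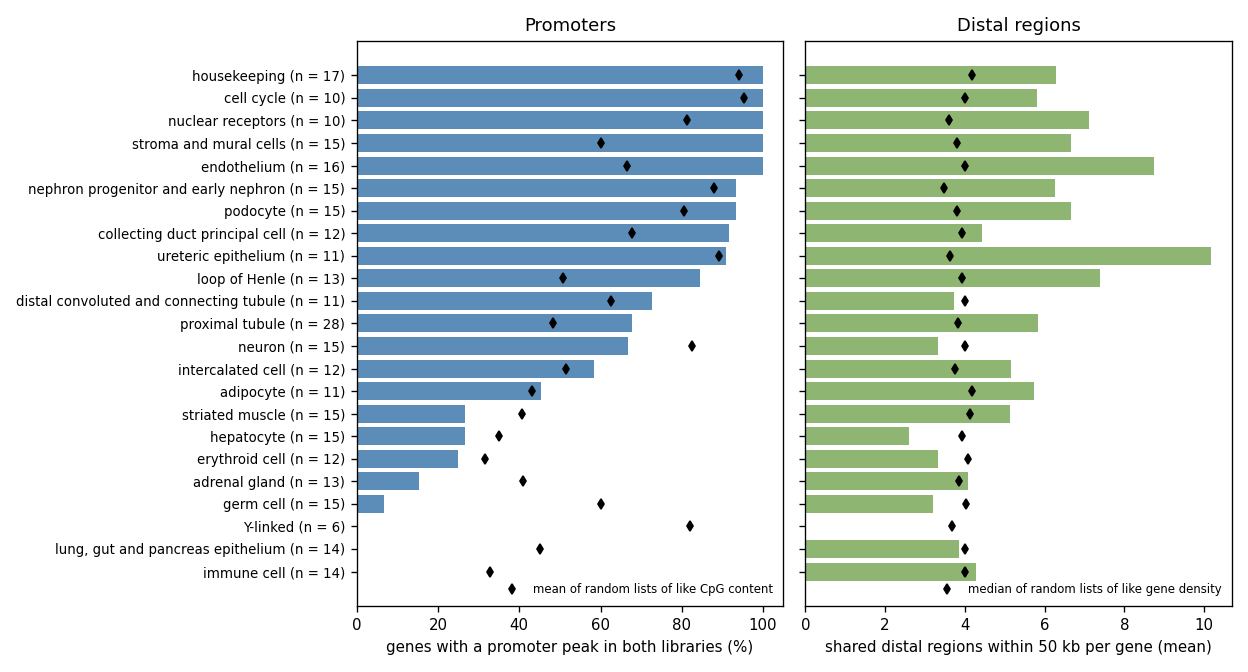
Left, share of each list's genes with a promoter peak in both libraries (x axis, %; bars) and the mean of CpG-matched random lists (diamonds); right, mean number of shared distal regions within 50 kb per gene (bars) and the median of random lists of like gene density (diamonds). Endothelium (100% of promoters, 8.75 distal regions) and ureteric epithelium (10.2 distal regions) stand farthest above the random lists on the right.

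The 10 strongest shared distal regions lay at least 10233 bp from the nearest protein-coding TSS, and several held repeated sequence. The strongest, on chromosome X from 169998061 to 169998420 in an intron of Mid1, a microtubule-associated ubiquitin ligase gene, had signals of 73.9 in replicate 1 and 19.2 in replicate 2. In it, 100% of the words of 32 bases occurred more than once in the genome, with a median of 6 copies. A region in an exon of Cers5, a ceramide synthase gene (chromosome 15, 99735641 to 99736060), had 23.6 and 53.4 and no repeated word. The region in an exon of Lars2, the mitochondrial leucyl-tRNA synthetase gene (chromosome 9, 123461901 to 123462080), had 58.2 and 17.2 with 57.0% repeated words. A region 35530 bp from Pak3 (chromosome X, 143482981 to 143483140) had 12.2 and 57.9 with 25.6%. A region 17903 bp from Tfap4 (chromosome 16, 4541841 to 4542060) had 37.4 and 15.4, and one 14825 bp from Zfp395 (chromosome 14, 65343681 to 65344020) had 38.6 and 12.9. Another, 72635 bp from Irf2bp2 (chromosome 8, 126666481 to 126666760), had 31.7 and 13.3, and none of these 3 held a repeated word. Others of the 10 were nearest to Igf2bp3 (36.4 and 12.7, with 87.9% repeated words) and Cstad (36.1 and 12.7).

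Among consensus sequences that exceeded all their shuffled versions in distal open regions, CTCF, NFI and HNF1 had the highest ratios. The CTCF consensus CCASYAGRKGGC, bound by the factor that anchors chromatin loops, occurred 3791 times in 15.2 Mb of shared distal regions and 293 times in 30.4 Mb of flanks. This is a ratio of 25.9 per base (95% interval 23.0 to 29.2), against at most 6.33 for its shuffled versions. NFI followed at 8.66 (5.90 to 13.1), then HNF1, a factor of tubule epithelium, at 4.82 (2.88 to 8.32; shuffled at most 0.4999), and the cyclic-AMP response element at 2.97 (2.52 to 3.52). PU.1 (2.54), HNF4 (2.10), a factor of the proximal tubule, AP-1 (1.71), the glucocorticoid receptor palindrome (1.53), TEAD (1.52), MEF2 (1.40), FOX (1.13) and CDX (1.02, with an interval of 0.945 to 1.10 that includes 1) also exceeded all their shuffled versions. In all, 12 of 33 consensus sequences did, 4 of 11 kidney, 5 of 13 general and 3 of 9 from other tissues. Of those that did not, some had high ratios that their shuffled versions reached or passed, among them the E-box of MYOD (3.95, shuffled at most 5.999), NRF1 (3.70), RFX (3.39), TFCP2L1 (2.71), ETS (2.63) and SP/KLF (2.40), and MYOD passed with flanks 5 kb away (4.64). In the stronger 50% of regions RFX (2.83, shuffled at most 1.9997) and SP/KLF (2.66, at most 2.62) passed, as did DR1 (0.714) against 3 usable shuffled versions at 0. OCT passed there too (0.759, at most 0.731) and without replicate 2 (0.742, at most 0.741), and ISRE passed without replicate 2 (1.15, at most 1.12). GRHL (0.964), ESRR (0.873), SOX (0.990), OCT (0.734) and GATA (0.638) stood below 1. WT1, the podocyte factor, had a ratio of 5.14 that equalled its highest shuffled version, and exceeded all of them without replicate 1 (4.48, shuffled at most 3.17) and without replicate 2 (4.54, shuffled at most 4.29). Without replicate 2 HNF1 stood at 2.86 and NFI at 13.3. CDX did not pass without replicate 2 (0.924, shuffled at most 0.931) or in the stronger 50% of regions (0.937, at most 1.01), and NFI (10.2, at most 13.99) not with flanks 5 kb away. HNF4 (1.91, at most 2.46) did not pass in the stronger 50% of regions, and the glucocorticoid receptor sequence in neither of these settings (1.45 and 1.42).

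Footprints of the libraries overlapped less than the peaks did, and the CTCF consensus had the highest ratio in them. Of the footprints, 43.8% in replicate 1 and 50.9% in replicate 2 overlapped one in the other library. Within shared regions the shares were 59.2% and 59.8%, against 40.9% after replicate 1 footprints were moved at random inside the regions. Their median width was 11 and 10 bp, and 85.7% and 87.6% of them lay in peaks. In all shared regions with such footprints, promoter regions included, CTCF matches fell in shared footprints 3909 times. They lay clear of the footprints of both libraries 30 times, and all other matches were left out of both counts. The ratio was 695 per base (95% interval 486 to 1032, shuffled at most 8.25). NFI (130 and 2 matches) gave 347, with a counting interval from 94.1 to 2894, and RFX (71 and 2 matches) gave 189, from 50.5 to 1594, with 3 usable shuffled versions. NRF1 stood at 263 (132 to 613), the cyclic-AMP response element at 80.9 (60.7 to 110) and SP/KLF at 45.5 (42.0 to 49.4; shuffled at most 41.5). HNF1 stood at 14.6 (7.09 to 32.2), ETS at 12.9, YY1 at 10.2, NFY at 6.39, HNF4 at 4.17 and MEF2 at 1.21, with an interval of 0.851 to 1.70 that includes 1. DR1, the direct repeat bound by HNF4 and retinoid receptors, at 10.7, rested on 8 and 4 matches and on 3 usable shuffled versions, all at a ratio of 0, so its pass carries little information. Here 13 of 33, DR1 included, exceeded every shuffled version, 9 of 13 general, 3 of 11 kidney and 1 of 9 from other tissues. AP-1 (1.03), TEAD (1.5), GATA (0.494) and FOX (0.413) did not, and PAX and REST had too few matches. Without replicate 1 the CTCF ratio was 91.1 and without replicate 2 it was 225. NFI fell to 43.5 and 84.9, NRF1 to 57.2 and 121, RFX to 63.1 and 31.1, the cyclic-AMP response element to 28.6 and 24.4, and SP/KLF to 18.3 and 19.5. Without replicate 2 ETS fell to 6.66, YY1 to 6.23 and NFY to 4.002. HNF1 (4.76), HNF4 (2.64) and MEF2 (1.28) did not exceed all shuffled versions without replicate 2, nor did MEF2 without replicate 1 (1.43). Counting only matches wholly inside a footprint left HNF4 (0.867), YY1 (3.29) and MEF2 (0.169) short as well, and HNF1 fell to 2.91 on 6 matches inside, ETS to 5.55 and NFY to 1.83. RFX fell to 115 and DR1 to 4.002 in that count.

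**Figure D4:**
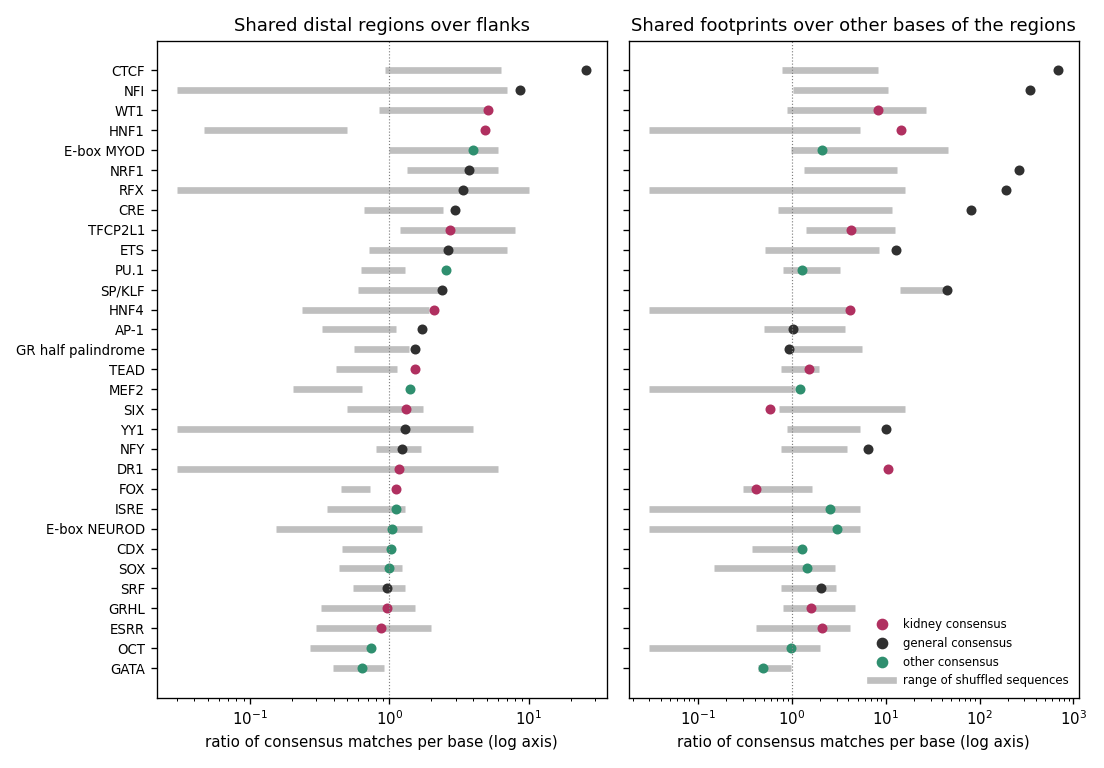
Ratio of consensus matches per base (x axis, log axis) in shared distal regions over flanks (left) and in shared footprints over bases that neither library marked (right). The right side covers all shared regions with such footprints, promoter regions included. Points are coloured by kind of consensus, and grey bars give the range of shuffled versions (bars that reach the left edge start at a lowest ratio of 0). CTCF stands highest on both sides, at 25.9 and 695, and HNF1 stands at 4.82 and 14.6.

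Endothelial promoters stood relatively higher in replicate 2, and principal cell promoters relatively higher in replicate 1. At promoters open in both libraries the deposited signal of replicate 1 was 2.55 times that of replicate 2 at the median, a log2 ratio of -1.35 with an SD of 0.66 over 14547 promoters. The ratios of lists and genes are relative to that median. The 16 endothelial promoters had a median log2 ratio of replicate 2 over replicate 1 of 0.82 against 0.02 in random lists of like signal (percentile 99.99), and the 15 stroma and mural cell promoters 0.53 against -0.01 (percentile 99.4). With random lists matched on CpG content as well as signal, endothelium stayed called (percentile 99.9), and stroma and mural cells did not (95.9). Before centring these medians were -0.53 and -0.82, so the deposited signal of these lists was still higher in replicate 1. The 11 principal cell promoters had -0.30 against 0.26 (percentile 1.3), the 10 ureteric epithelium promoters -0.51 (percentile 1.46) and 4 hepatocyte promoters -0.45 (percentile 1.08). The distal regions within 50 kb of these 3 lists did not stand low, at percentiles 67.03, 76.1 and 96.5 of random lists, against 99.1 for endothelium and 62.4 for stroma and mural cells. For distal regions the random lists were matched on the number of regions, not on signal or GC content. With promoters of 500 bp the ureteric and hepatocyte lists moved to percentiles 80.4 and 46.2. At 8.41% of promoters open in both the strongest peaks of the libraries did not overlap, and without these endothelium (99.99), stroma and mural cells (99.8), principal cell (1), ureteric (1.59) and hepatocyte promoters (1.32) were still called and neuronal promoters were as well (-0.43, percentile 0.52). Proximal tubule (0.48; percentile 96.6), loop of Henle (0.50; 88.9), erythroid (0.55, on 3 promoters; 89.3), nuclear receptor (0.26; 74.97) and nephron progenitor promoters (0.24; 77.9) were within the range of random lists. So were intercalated cell (0.22; 24.4), adipocyte (0.20; 40.6), muscle (0.18; 30.2), distal convoluted tubule (0.13; 12.1), podocyte (0.10; 44.2), neuron (0.07; 24.6), cell cycle (0.00; 60.7) and housekeeping promoters (-0.09; 29.0). Among single listed genes, the largest ratios toward replicate 2 were at the lactate transporter gene Slc5a12 (2.47; signals 0.246 in replicate 1 and 0.536 in replicate 2), the proteoglycan gene Dcn (1.77; 0.604 and 0.810) and the endothelial receptor gene Tie1 (1.77; 2.11 and 2.81). Those toward replicate 1 were at Itih1 (-1.73), Apob (-1.51) and Chga (-1.42). With 1 library on each side, no difference between animals was tested.

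**Figure D5:**
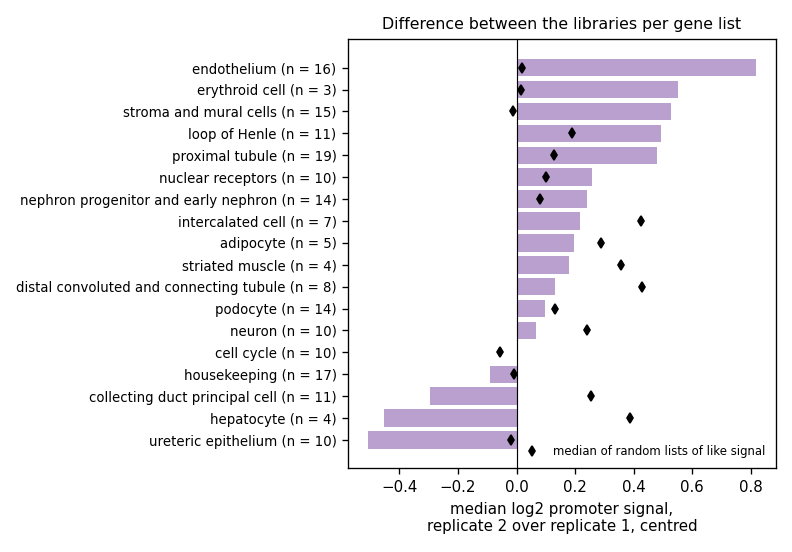
Median log2 ratio of promoter signal, replicate 2 over replicate 1, centred on the median of all promoters (x axis), for each list's promoters open in both libraries (bars, number in brackets) and for random lists of like signal (diamonds). Endothelium, at 0.82, stands highest and ureteric epithelium, at -0.51, lowest.

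The sex chromosomes followed the female label at the Y-linked genes. None of the 6 Y-linked genes, among them Ddx3y, Uty and Kdm5d, which are broadly active in male tissue, had a promoter peak in either library, while all 17 housekeeping genes did. Fisher's exact test of the Y-linked list against all other genes gave an adjusted p of 0.00509. The X chromosome had 25.5 peaks per Mb in replicate 1 and 25.1 in replicate 2, which was 0.385 and 0.453 times the density of the autosomes (66.2 and 55.5 per Mb, lowest single autosome 50.5 and 43.8). With the stronger 50% of peaks these ratios were 0.277 and 0.247, so that the order of the libraries turned, as with the shorter peak lists (0.355 and 0.330). The Y chromosome had 38 peaks in replicate 1 and 108 in replicate 2, with median signals of 0.316 and 0.115, in 112 regions of which 27 were open in both.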

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

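The shorter peak lists, a single TSS per gene, and library ratios only where the strongest promoter peaks overlap were tried after the data had been seen; the other alternatives were planned. Of the values and counts that answer a comparison 32 stayed close to the reported size (counts within 1.5 times, shares within the SD between libraries) and 14 moved. Many are counts of called lists, which can stay while the lists change: with promoters of 500 bp 13 lists were called for promoter peaks as before, but podocyte and nephron progenitor lists were no longer among them and nuclear receptors and cell cycle were. Among the values of single lists and consensus sequences 630 were unchanged in call, 35 gained it, 48 lost it and 2 reversed, over the settings in which each was run, leaving out scaling to each library's total. Mean peak overlap was 54.1% with a reciprocal overlap of 50% and 76.1% with the stronger 50% of peaks (64.2% as reported). Footprint overlap was 32.7% with a reciprocal overlap of 50% (47.4% as reported); a stricter overlap rule can only lower these shares. The correlation of log2 signal was 0.83 over shared regions and 0.53 by ranks (0.56 as reported), since regions open in 1 library drop out of the first. The promoter share was 17.7% within 500 bp and 29.9% within 2000 bp, which follows from the width of the window, and 34.3% with the stronger 50% of peaks and 30.9% with the shorter peak lists, where the cause was not tested. Matching on CpG content, which also put a resampling test in place of Fisher's test, gave 7 lists with a call for promoter peaks in place of 13. Of the 7, 6 were among the 13 and the loop of Henle list was newly called. For promoter signal, leaving out the matching gave 10 calls in place of 5. With promoters of 500 bp, 3 lists in place of 5 differed between the libraries, and the cause was not tested. Where the strongest peaks overlap 6 did, the neuronal list being new. The density of X over autosome peaks, a mean of 0.419, was 0.342 with the shorter lists and 0.262 with the stronger 50% of peaks, and the cause was not tested. The distal convoluted and connecting tubule list, 72.7% open as reported, was 27.3% open and below other genes with the stronger 50% of peaks and likewise 27.3% with the shorter lists. The cause was not tested beyond the loss of weak peaks that both settings make. Counts of consensus sequences above all shuffled versions ranged from 11 to 14 in distal regions and from 10 to 13 in footprints. The comparison planned with the stronger 50% of footprints was not run, because the footprint score is 1 constant. Scaling to each library's total adds the same amount to every promoter, so that it could not move a percentile and tests nothing. No paired analysis was possible because there is 1 group. Depth is unknown, so a region open in 1 library only was not shown to be closed in the other, and the weakest peaks, with 2.32% shared in replicate 2, are the least certain.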

Other observations

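The tests of male animals, of Y regions without shared words, and of regions of unlike GC content or unlike signal were chosen after their results had been seen. So was the share of the stromal difference that CpG content had to remove to be read as its cause. Regions open in 1 library and the difference between promoter and distal folds had also been looked at before the tests on GC content were set. The Hox genes were chosen after the Hoxa9 window had been seen.

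Distal open regions were not spread evenly, and the 10 densest 50 kb windows held from 20 to 32 of them. Whether these windows favoured any class of gene was not tested. The window with the most shared distal regions, 32 against a median of 2 in windows with at least 1, was on chromosome 17 from 84150001 to 84200000 and held the TSS of Zfp36l2, an RNA-binding regulator of mRNA decay. The Hoxa cluster followed with 29 (chromosome 6, 52200001 to 52250000). Next came a window nearest to Ptgis, the prostacyclin synthase gene, with 27 (chromosome 2, 167250001 to 167300000), and a window with Cdc6 and Rara, the retinoic acid receptor gene, with 24 (chromosome 11, 98900001 to 98950000). Windows at Tns1 (23 and 20), Nfic, an NFI family gene (23), Hspg2, the perlecan gene (22), and Nr2f2, a nuclear receptor gene (21), were also among the 10 densest.

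Hox genes, which pattern the body axis, were open at 34 of 39 promoters in both libraries. Paralogue groups 2, 3 and 5 to 11 were open throughout. Group 10 had the highest median signal in replicate 1, 13.2, and group 7 in replicate 2, 4.81 against 4.77 for group 10, with Hoxc10 at 17.3 and 5.59, Hoxa10 at 13.2 and 3.24 and Hoxd10 at 7.19 and 4.77. Group 11, in which Hoxa11 and Hoxd11 act in kidney formation, was open but low. Hoxa11 stood at 2.03 and 1.68, Hoxc11 at 1.47 and 0.613 and Hoxd11 at 1.57 and 0.714, when the median of all open promoters was 8.43 and 2.96. At the posterior end Hoxa13 and Hoxc12 had no peak, Hoxd13 had one in replicate 1 alone (1.05), and Hoxb13 (0.524 and 0.468) and Hoxd12 (0.567 and 0.362) were weak, whereas Hoxc13 was open at 3.14 and 1.91. Hoxb1 was open in replicate 1 alone (0.513) and Hoxd4 in replicate 2 alone (0.743).

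Peaks on the Y chromosome appeared in both libraries labelled female. Whole libraries from male animals are argued against by 0 of 6 Y-linked promoters with a peak in either library, although a small share of male cells was not excluded. Sequence shared with other chromosomes may account for part of the peaks: the median Y region had 46.2% of its words of 32 bases on another chromosome, against 2.17% for random Y segments, and the strongest (90744481 to 90744820) had 66.3%, with signals of 12.5 and 1.45. The random segments are an unlike comparison, since a median of 100% of their words occurred more than once in the genome, against 64.6% for the Y regions. For 19 of the 112 regions no word was found on another chromosome of the reference sequence. Their signals reached 0.920 in replicate 1 and 1.33 in replicate 2. For them identical sequence on those chromosomes is argued against. Identical sequence elsewhere is not decided, since sequence outside the reference chromosomes, such as that of the CAST strain, was not searched. The regions with these highest signals (90739601 to 90739900 and 90738941 to 90739260) lay close to the strongest Y region. For the other regions shared sequence cannot be told apart from other sources, since the median fell between the limits set for and against it. No biological explanation was tested.

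Endothelial and stromal promoters stood higher in replicate 2, by 0.82 and 0.53 on the centred log2 scale. Promoter CpG content as the whole cause is argued against for endothelium, which stayed at percentile 99.94 among random lists matched on signal and CpG content; for stroma the call ended at percentile 95.905, because the random lists moved up, from a median of -0.01 (95% of lists from -0.41 to 0.42) to 0.15 (-0.27 to 0.57), while the list's own 0.53 was unchanged, and since this removed 30.6% of the difference, CpG content cannot be told apart from other sources there. A larger share of endothelial cells in replicate 2 remains a candidate explanation that the distal regions could not decide. The 140 distal regions near the 16 endothelial genes stood high, with a median of the gene medians of 0.04 against -0.28 in random lists (percentile 99.09). However, these random lists were matched only on the number of distal regions, while distal ratios also varied with signal and GC content. The striated muscle list stood low in the same test (percentile 0.77). For stromal cells the distal regions, at -0.21 against -0.27 (percentile 62.42), decide nothing. Dissection, the make-up of the tissue and the animals themselves cannot be separated with 1 library each, and no biological difference was given by the design.

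Replicate 1 gave the higher deposited signal, by 2.32-fold at shared promoter regions and 1.31-fold at shared distal regions, a gap of 0.82 on the log2 scale, though in the weakest signal decile replicate 2 was higher (fold 0.864). Fewer reads behind replicate 2, lowering all regions by 1 factor, are argued against as the whole cause: the fold rose from 1.78 in the sixth signal decile to 2.81 in the ninth, a log2 step of -0.66 (95% bootstrap interval -0.70 to -0.63), and was 2.64 in the tenth, and the smaller step size of replicate 2 would mean more counts there if the signal is counts scaled to a fixed total, although at equal mean signal distal and promoter regions differed by only 0.206 (0.18 to 0.23) and the highest and lowest GC deciles by -0.179 (-0.23 to -0.12), close to the limit of 0.2 that had been set. GC content of the regions may account for part of the gap, but it could not be separated from signal level. The fold rose from 1.13 in the lowest GC decile to 3.10 in the highest. At equal mean signal that rise was much smaller, as the -0.179 above shows. Matching on GC content left 30.4% of the gap, between the limits set for and against it. Matching on mean signal alone left 25.1%, and matching on GC content and signal together left 6.06%. GC content, signal level and promoter identity remain tied together in these regions, and what made the libraries differ by GC content or by signal was not tested. No biological explanation was tested.

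A hypothesis fixed in advance was that HNF1, HNF4 and DR1 sequences lie near proximal tubule genes, where those factors act. Of the 154 shared distal regions within 50 kb of proximal tubule genes 4 (2.60%) held such a consensus, against 0.778% of the other shared distal regions, an odds ratio of 3.40 (Fisher's exact test, two-sided, p = 0.0334). The direction was that of the hypothesis, but the count is 4 regions, and after adjustment over the 22 lists with such regions the p was 0.735 (Fisher's exact test), so the association may be chance.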
